A study of Mus musculus with 6 samples.

How the data were processed

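RNA from sorted mouse HSC was compared between 3 control pools and 3 CDKO pools. Per the labels, RNA was isolated with a micro column kit, amplified with the SMARTer ultra low input chemistry and made into Nextera XT libraries. TopHat2, HTSeq and DESeq2 are named, with no version, per the submitters' processing notes, which also name the build mm10. The notes do not state the gene annotation, and the labels do not state the markers used for the sort. The deposited table lists 24062 genes with a value for each library.

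The deposited values per library are counts scaled to 1000000 (CPM), in units of the library's own total, checked by column sums. Dividing each by its smallest step gave whole reads for 99.9989% of the values above 0, to within 0.01 of a read. The deposited baseMean is a signal averaged over the 6 libraries after size factor scaling, and it was recomputed from the recovered reads to within a relative difference of 3.25e-09. The deposited log2 fold change and its standard error are on the log2 scale and set control over CDKO, so the sign was turned before use. The deposited stat column is a score, the log2 fold change over its standard error. The deposited p-value and adjusted p-value columns are the authors' DESeq2 results, used here only for a count set beside the tests run here.

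Genes were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with eBayes and a mean-variance trend, for CDKO minus control with no other term. The Benjamini-Hochberg adjusted p threshold was 0.05, two-sided. This test, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The filter was fixed, for a table of normalized values such as CPM, as a mean of at least 10 over the 6 libraries, with no unit given. It was read on the scale of recovered reads, which is a mean of 0.255 CPM at the mean depth, since the stricter alternative of 50 was stated on that scale. That reading was made after values had been seen, including those of Cebpa. The reading as 10 CPM, under which Cebpa is not tested, is the more direct reading of that plan. It was run only as an alternative added later. Of the listed genes 7104 had no read in any library, 12 carried a date in place of a symbol and 2 shared a symbol. The 12 date-named genes were kept out of the tests because the symbols behind them cannot be recovered.

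The genes named are Nr4a1, Nr4a2, Nr4a3, Cebpa, Gt(ROSA)26Sor and Esr1 whatever their values. Next come the 12 highest and 12 lowest log2 differences among genes past the threshold with no overlap between groups. For each list described, up to 4 genes with the smallest p are named, and further members past the threshold within their group. Members named as not passing, among them Gata1, Elane, Prtn3, Mki67 and Cebpb, were chosen after their values were seen. The further list members named in the text beyond the fixed rule were revised several times after their values and their behaviour under the alternatives had been seen, and some that changed side were dropped, so the share of named genes that kept their call is not an unbiased measure of stability. Some list members are not reported here. In all, 33 lists were fixed, of which 30 had at least 3 tested genes. Of 690 list entries 667 were found, 4 of them under an older symbol. Lists were tested with camera (inter-gene correlation preset to 0.01), with camera using an estimated correlation, and with fry, each adjusted over the 30 lists. The fry test asks whether a list's genes move, on balance, one way, and its mixed form whether they change in either direction. Neither compares them with other genes. Folds are ratios of mean CPM, errors are SD over 3 pools or the standard error of the limma coefficient, and no fold is given where a group mean lies under the floor of 3 counts, unless that group is at 0. Coordinates are from the RefSeq annotation of the mouse genome that matches mm10.

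Alternatives were a block on replicate number, leaving out each library, no filter, a mean of at least 50 reads, TMM or quantile scaling, pseudocounts of 0.5 and 5, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a 1.5-fold minimum and an adjusted p threshold of 0.1. Added after the data were seen were the mean of at least 10 CPM and a loess correction of each library for GC content and transcript length, which 99.1% of tested genes had. The labels do not say that replicate numbers pair the libraries. The main test was fixed beforehand without pairing. The correlation of deviations between libraries with the same number was 0.0518, 0.0483 and -0.0120. Between libraries of the 2 groups with different numbers it ran from -0.0651 to 0.0264. These values do not settle whether the numbers pair libraries. Within groups the correlation of log2 values was at least 0.993, and between groups it was at most 0.955.

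The tests were tested on simulated data in 20 draws with the depth and spread of these libraries and 200 changed genes among 13734. With the spread of each gene, limma recovered 18.9% of genes changed 1.2-fold, 59.6% at 1.5-fold, 74.2% at 2-fold and 87.8% at 4-fold, and 7.39% of its calls were false. In those draws 6.95% of the calls by edgeR and 21.3% of those by DESeq2 were false. With the trended spread, 4.27% of the limma calls and 4.98% of the edgeR calls were false. In the data 9097 genes passed, far more than the 200 changed in a draw, so these recovered and false shares do not carry over. A raised set was found in 20 of 20 draws by camera and by fry, and of 1000 random sets camera called 3.4% and fry 13.3%. Simulated genes were drawn independently, and random sets could hold changed genes. These shares therefore do not check the preset correlation or give false call rates for the lists. Estimated correlations in the data were 0.209 for interferon response and 0.643 for G2 and mitosis.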

Results

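RNA was sequenced from hematopoietic stem cells (HSC), the cells that renew the blood, sorted from mice of 2 genotypes. Per the labels, mice of both groups carried floxed Nr4a1 alleles and lacked Nr4a3 from birth. The CDKO mice also carried a construct labelled Rosa26-ERt2, which by background is a tamoxifen-activated Cre recombinase that removes floxed sequence, and the control mice did not. Both groups were given tamoxifen at 120 mg per kg, once a day for 4 days, and HSC were sorted on day 5. Each library came from a pool of 3 to 5 mice, and each group had 3 libraries. The control libraries held 39111308, 36464747 and 42348692 counted reads, and the CDKO libraries held 32863805, 41475747 and 42772261. At these depths a count of 0 allowed a level of at most 0.0701 to 0.0913 counts per 1000000 (CPM), by library (3 counts, counting error only). The single comparison, CDKO against control, addressed what changed in HSC when Nr4a1 was deleted in animals already without Nr4a3. Cre and the Nr4a1 deletion came in the same libraries, so their effects were not separated by the design.

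Nr4a1, the floxed nuclear receptor gene (mm10 chromosome 15, 101253902 to 101274795), fell in CDKO HSC but was not lost from the gene-level counts. Its level was 13.8 ± 1.18 CPM (SD, n = 3) in control and 9.13 ± 0.623 CPM (SD, n = 3) in CDKO pools, a log2 difference of -0.55 (SE 0.12, limma adjusted p = 0.00204), and it was lower in 3 of 3 CDKO pools. Counts per gene do not separate exons that were removed from exons that were kept, so this difference does not measure how much of the allele was deleted. Nr4a3 (chromosome 4, 48045078 to 48086447) had 0 reads in all 6 libraries. Nr4a2, the remaining member of the family (chromosome 2, 57106830 to 57124003), was measured at 3.86 ± 0.282 CPM in control and 2.43 ± 1.22 CPM in CDKO pools and did not pass the test (log2 difference -0.57, limma adjusted p = 0.0547). It passed with replicate number as a block (limma adjusted p = 0.0314) and without CDKO replicate 3 (limma adjusted p = 0.0115). It passed as well with a pseudocount of 5 (limma adjusted p = 0.0396) and after a correction for GC content and transcript length (limma adjusted p = 0.0497). Over its alternatives the adjusted p (limma, edgeR or DESeq2) ran from 0.0115 to 0.216. Leaving out 1 library at a time, its log2 difference ran from -0.798 to -0.250, with CDKO pools at 1.10, 2.72 and 3.48 CPM. Of the 2 genes that the construct's label points to, Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077244) fell from 30.02 ± 1.57 to 24.3 ± 2.66 CPM (limma adjusted p = 0.0195) and Esr1, the estrogen receptor gene (chromosome 10, 4611989 to 5005633), from 16.8 ± 1.58 to 11.4 ± 4.93 CPM (limma adjusted p = 0.0324). Both of these calls were lost without control replicate 2, where the limma adjusted p was 0.0773 for Gt(ROSA)26Sor (0.00575 to 0.0773 over its alternatives) and 0.0904 for Esr1 (0.000612 to 0.136 over its alternatives). They were lost as well without control replicate 3 and without CDKO replicate 3, and also without CDKO replicate 2 for Gt(ROSA)26Sor and without CDKO replicate 1 for Esr1, which was not called by edgeR (adjusted p = 0.0768), by DESeq2 (adjusted p = 0.0517) or with no filter either. Gt(ROSA)26Sor was not called with quantile normalization. Both were counted as mouse genes and not as the construct, so these values do not show which pools carried it.

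**Figure D1:**
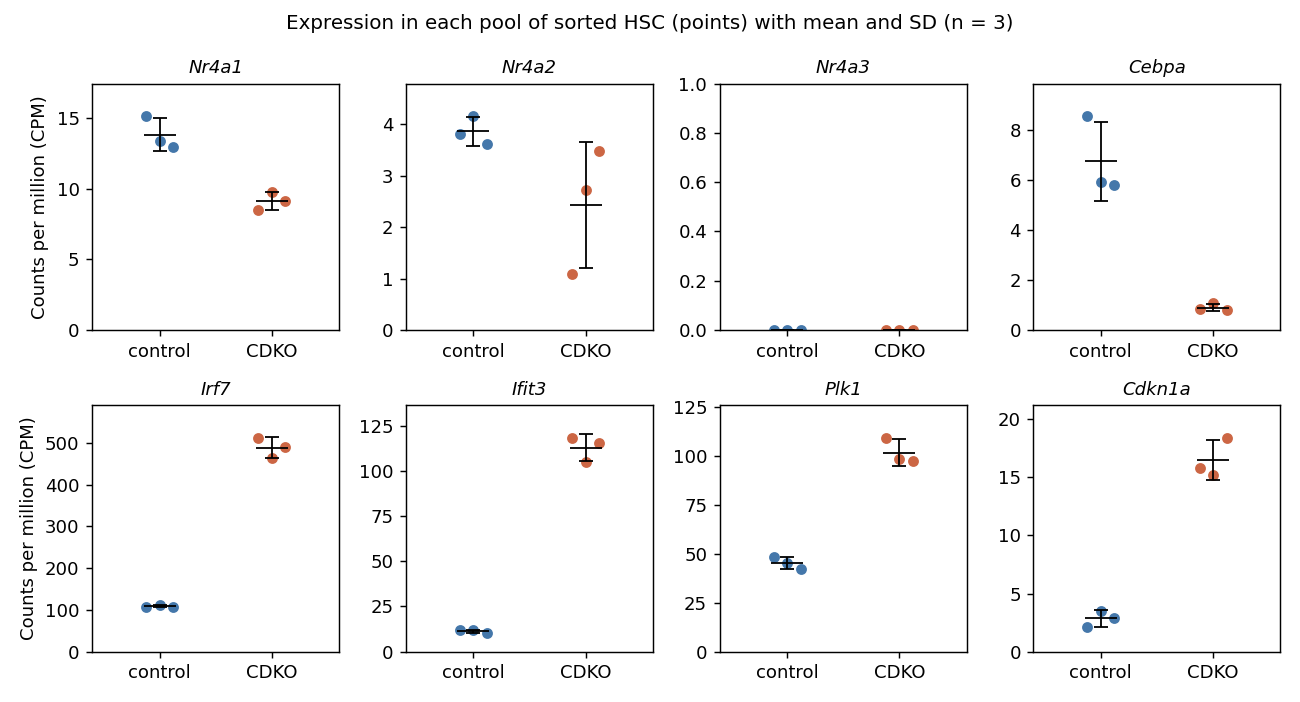
Expression of 8 genes in each of the 6 pools, in CPM on linear axes that start at 0. Points are pools of control or CDKO mice, long bars are group means and error bars are the SD (n = 3). Nr4a1 was 13.8 CPM in control and 9.13 CPM in CDKO pools, Cebpa 6.75 and 0.892 CPM, and Irf7 109 and 489 CPM.

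A large part of the transcriptome differed between the 2 groups. The labels name no preparation batch, so a difference in preparation or sequencing shared within a group could not be told apart from genotype. Of 13734 genes tested, 9097 passed the threshold (limma, adjusted p under 0.05), with 4265 higher and 4832 lower in CDKO pools. Which side held more genes depended on the scaling, with 4691 higher and 4444 lower after quantile normalization, and 5065 higher and 4134 lower after a correction for GC content and transcript length. A change of at least 1.5-fold was seen in 3999 of them, 1645 higher and 2354 lower, and of at least 2-fold in 1821, 722 higher and 1099 lower. The 3 CDKO values lay on one side of all 3 control values for 9703 genes, 70.6% of those tested, against the 10% that chance gives. The authors' deposited table gave 9291 genes with an adjusted p under 0.05, and 8783 genes passed in both, all 8783 in the same direction. Both results come from the same libraries, so their agreement is not independent evidence.

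The genes that rose most, ranked by the difference in log2(CPM + 1) among those whose pools did not overlap, began with Pde10a, which encodes a cyclic nucleotide phosphodiesterase, at 0.448 ± 0.540 CPM in control and 25.7 ± 2.80 CPM in CDKO pools. Zfp365, Ifi204, Trpm6, Ifit3, Spry4, Flt4, Itga1, Tlr3, AI414108, Car5b and Cxadr completed the 12 highest. Among them Spry4, an inhibitor of receptor tyrosine kinase signalling, rose from 1.201 ± 0.486 to 18.9 ± 2.61 CPM, and Tlr3, a receptor for double-stranded RNA, rose from 1.17 ± 0.113 to 17.3 ± 2.02 CPM. The 12 lowest were Prss34, Epx, Ngp, S100a9, Mcpt8, S100a8, Retnlg, Ermap, Slc4a1, Camp, Mmp9 and Ltf. Prss34, a basophil protease, fell from 163 ± 21.6 to 0.179 ± 0.263 CPM, and Slc4a1, the anion exchanger of the red cell membrane, fell from 53.7 ± 3.95 to 1.76 ± 0.273 CPM (limma adjusted p = 1.83e-09). Passing the limma test with 3 of 3 CDKO pools on the stated side was the condition for choosing these 24 genes, not a further result. The order holds for that scale only, which draws in genes near 0.

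Cebpa, the transcription factor that directs HSC progeny toward the granulocyte lineage (chromosome 7, 35119293 to 35121928), fell 7.56-fold. It stood at 6.75 ± 1.57 CPM in control and 0.892 ± 0.146 CPM in CDKO pools (SD, n = 3), a log2 difference of -2.02 (SE 0.17, limma adjusted p = 2.33e-06), and was lower in 3 of 3 CDKO pools. Of 6 measured members of the C/EBP family 5 fell, also 5 adjusted over the list alone. Cebpg fell from 94.6 ± 7.57 to 57.5 ± 4.39 CPM and Ddit3, a stress-induced family member, from 17.4 ± 1.86 to 9.97 ± 1.80 CPM. Cebpe, needed for late granulocyte maturation, and Cebpd fell as well, while Cebpb was 49.9 CPM in control and 52.9 CPM in CDKO pools and did not pass. Neither edgeR (adjusted p = 0.0996) nor DESeq2 (adjusted p = 0.108) called Cebpe, and its call was lost with quantile normalization and without control replicate 2, control replicate 3, CDKO replicate 1 or CDKO replicate 2 (without each of these libraries, limma adjusted p from 0.0570 to 0.0847; 0.00672 to 0.143 over all its alternatives). The Cebpd call was lost without control replicate 2 (limma adjusted p = 0.0631), CDKO replicate 1 (limma adjusted p = 0.0533) or CDKO replicate 2 (limma adjusted p = 0.0504). As a set, the family did not pass limma's camera test against other genes (median log2 difference -0.70, adjusted p = 0.105). Neutrophil markers fell in the same pools, by a median log2 difference of -3.99. Whether cells other than HSC held part of the Cebpa reads in control pools was not tested.

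Genes of S phase and of G2 and mitosis were mostly higher in CDKO HSC. Of 36 genes of G2 and mitosis 26 rose and 3 fell, 29 in all adjusted over the list alone, with a median log2 difference of 0.51 (camera adjusted p = 1.18e-05; adjusted p = 0.647 with an estimated correlation). Plk1, a kinase that drives entry into mitosis, rose from 45.3 ± 3.12 to 102 ± 6.70 CPM, Racgap1, which acts in the division of the cell body, from 80.2 ± 2.35 to 142 ± 6.30 CPM, and Tacc3, a spindle protein, from 86.2 ± 3.04 to 144 ± 6.79 CPM. Anln, Cenpf and Bub1b fell, and Mki67, a general marker of cycling cells, was 327 ± 18.4 CPM in control and 332 ± 23.4 CPM in CDKO pools and did not pass (limma adjusted p = 0.775). Of 37 genes of S phase and DNA replication 26 rose and 4 fell, 30 in all adjusted over the list alone, with a median log2 difference of 0.24 (camera adjusted p = 0.000572; adjusted p = 0.633 with an estimated correlation). Pola1, the catalytic subunit of the polymerase that primes replication, rose from 64.7 ± 2.66 to 107 ± 5.79 CPM, and Mcm6, a subunit of the replicative helicase, from 723 ± 36.0 to 990 ± 40.9 CPM. Cdc6, which loads that helicase, Chaf1a, Rrm2 and Pole were the 4 that fell, of which Chaf1a and Pole did not pass after a correction for GC content and transcript length (limma adjusted p = 0.573 and 0.698, the highest over their alternatives). After the same correction Mki67 did (log2 difference 0.17, limma adjusted p = 0.0458; 0.0458 to 0.983 over its alternatives).

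The interferon response genes rose together. Of 47 measured genes 42 rose and 1 fell, 43 in all adjusted over the list alone, with a median log2 difference of 0.75 (camera adjusted p = 1.66e-16), while the list did not pass with an estimated correlation (adjusted p = 0.430). Irf7, a transcription factor that amplifies interferon production, rose from 109 ± 1.75 to 489 ± 24.97 CPM (log2 difference 2.16, limma adjusted p = 3.73e-10). Ifit3 and Ifit1, antiviral proteins that respond to interferon, rose from 11.4 ± 0.806 to 113 ± 7.25 CPM and from 38.1 ± 2.19 to 185 ± 10.2 CPM. Oas2, a sensor of double-stranded RNA, rose from 39.5 ± 1.78 to 192 ± 6.75 CPM. Irf8, which besides its role in interferon signalling directs monocyte development, was the 1 gene that fell, from 40.9 ± 3.63 to 15.6 ± 2.40 CPM. Irf9, Irf1, Isg20 and Parp14 did not pass, though Irf9 did after the GC and length correction and without CDKO replicate 2 (limma adjusted p = 0.0281 and 0.0383; 0.0281 to 0.313 over its alternatives).

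Genes of NF-kB signalling and inflammatory cytokines went both ways. Of 33 measured genes 14 rose and 10 fell, 24 in all adjusted over the list alone, and the list did not pass as a set (median log2 difference 0.12, camera adjusted p = 0.520). Cxcl10, a chemokine that is also an interferon target, rose from 17.3 ± 0.281 to 55.7 ± 7.53 CPM. Il6 had 0 reads in the control pools and 1.68 ± 0.227 CPM in CDKO pools, at least 18.4-fold higher when compared with the largest floor of a library, 0.0913 CPM (3 counts). Tnfaip2, a target of tumor necrosis factor, fell from 105 ± 4.12 to 55.2 ± 2.05 CPM, and Il12a, a subunit of interleukin-12, fell from 46.9 ± 1.42 to 21.3 ± 1.04 CPM.

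HSC identity genes were split. Of 32 measured genes 10 rose and 16 fell, 26 in all adjusted over the list alone, with a median log2 difference of -0.17 and no call as a set (camera adjusted p = 0.440). That median ran from -0.206 to -0.101 leaving out 1 library at a time, and was -0.0622 after the GC and length correction. Esam, an adhesion molecule of the HSC surface, rose from 191 ± 4.74 to 265 ± 1.28 CPM, and Tek, the receptor for angiopoietin, rose from 70.9 ± 7.03 to 122 ± 1.01 CPM. Ly6a (the surface protein Sca-1, itself an interferon target), Vwf and Slamf1 also rose. Ctnnal1, a gene used to mark HSC in reporter mice, fell from 85.3 ± 6.72 to 42.2 ± 4.82 CPM, and Fgd5, another such reporter gene, fell from 122 ± 1.18 to 72.8 ± 8.29 CPM. Kit, the receptor for stem cell factor, and the transcription factor genes Hlf and Mecom were among the other genes that fell.

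Genes of the blood lineages moved apart. Of 22 measured genes of megakaryocyte differentiation 16 rose and 3 fell, 19 in all adjusted over the list alone (median log2 difference 0.50, camera adjusted p = 0.00113; adjusted p = 0.430 with an estimated correlation). Pf4, platelet factor 4, rose from 27.8 ± 1.73 to 82.0 ± 7.45 CPM and Ppbp, another platelet chemokine, from 1.99 ± 0.572 to 13.3 ± 0.792 CPM. Nfe2, a transcription factor of the lineage, and Thbs1 were among those that fell. Of 20 genes of erythroid differentiation 1 rose and 14 fell, against 16 in all adjusted over the list alone (median log2 difference -1.16, camera adjusted p = 0.000572; adjusted p = 0.430 with an estimated correlation). Klf1, the master regulator of red cell genes, fell by 2.06 on the log2 scale, to 11.2 ± 0.632 CPM, and Rhd, a red cell surface antigen, fell from 28.5 ± 2.16 to 0.984 ± 0.168 CPM. Apoe, a lipid carrier expressed in many cells, was the 1 that rose. Gata1, a regulator of both lineages, was 30.3 ± 1.97 CPM in control and 31.5 ± 2.13 CPM in CDKO pools and did not pass.

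All 13 measured neutrophil markers fell in the pools where cell cycle, interferon and megakaryocyte genes rose, 13 adjusted over the list alone (median log2 difference -3.99, camera adjusted p = 9.76e-07; adjusted p = 0.464 with an estimated correlation). Ngp and Ltf, proteins of neutrophil granules, fell from 240 ± 32.8 to 6.99 ± 5.90 CPM and from 209 ± 33.6 to 14.5 ± 11.2 CPM, and Retnlg fell from 21.9 ± 3.41 to 0.119 ± 0.181 CPM. Within the CDKO group, 12 of the 13 markers were highest in replicate 3, and without that library the log2 difference was -5.31 for S100a8, in place of -4.48, -5.76 for S100a9, in place of -5.00, and -4.66 for Camp, in place of -4.05. Of 9 measured mast cell and basophil markers 7 fell and 1 rose, 8 in all adjusted over the list alone (median log2 difference -1.92, or -1.81 with genes at 0 in a group set to their bound; camera adjusted p = 0.00603; adjusted p = 0.464 with an estimated correlation). Mcpt8, a basophil protease, fell from 37.0 ± 4.28 to 0.677 ± 1.147 CPM, with 2.00 CPM in CDKO replicate 2, 0.0304 CPM in replicate 1 and 0 reads in replicate 3. Ms4a2, Prss34 and Fcer1a were also highest in CDKO replicate 2, and without that library the log2 difference of Mcpt8 was -5.22, in place of -4.70. Gzmb, a granzyme that is also a marker of cytotoxic lymphocytes, was the 1 that rose, from 0 reads to 3.13 ± 0.420 CPM. Of 26 myeloid differentiation genes 8 rose and 13 fell, 21 in all adjusted over the list alone, with no call as a set (median log2 difference -0.36, camera adjusted p = 0.527; median 0.13 at a mean of 10 CPM, adjusted p = 0.819). Csf1r, the receptor for macrophage colony-stimulating factor, rose from 3.22 ± 0.626 to 21.5 ± 1.68 CPM, and Clec12a, a myeloid surface lectin, fell from 15.9 ± 1.42 to 2.99 ± 1.55 CPM. The granule protease genes Elane, at 21.0 ± 2.03 and 16.02 ± 12.8 CPM, and Prtn3, at 204 ± 11.99 and 193 ± 15.9 CPM in control and CDKO pools, did not pass, though Elane passed without CDKO replicate 3 (log2 difference -1.19, limma adjusted p = 3.00e-05; 3.00e-05 to 0.595 over its alternatives).

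**Figure D2:**
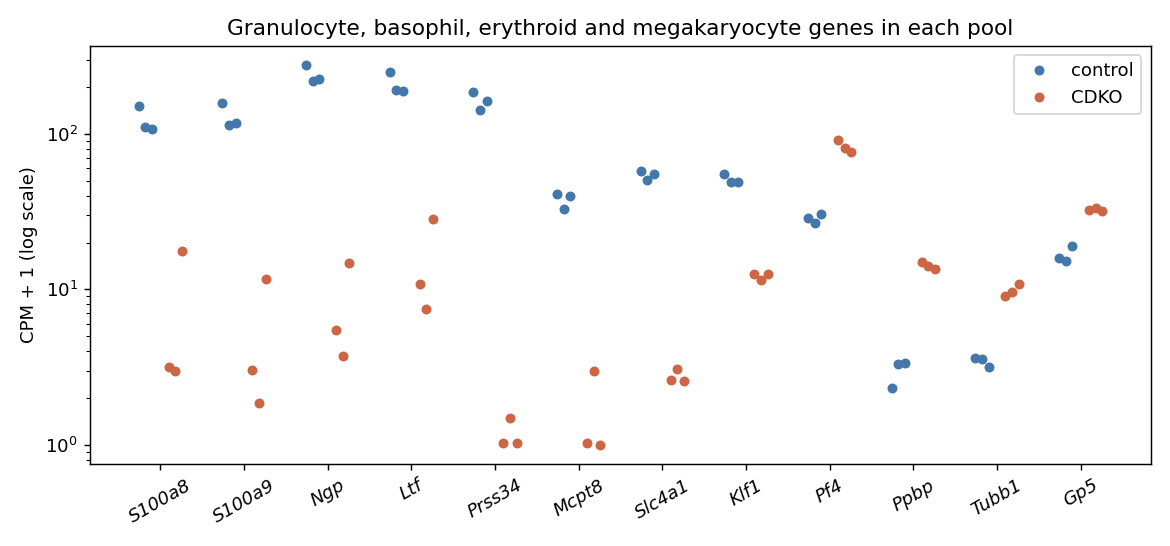
Expression of 12 lineage genes in each of the 6 pools (points, 3 per group), as CPM + 1 on a log axis. Among them Pf4 was higher in CDKO pools, at 82.0 against 27.8 CPM, and Slc4a1 was lower, at 1.76 against 53.7 CPM.

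Targets of p53, the transcription factor that responds to DNA damage, were more often higher than lower. Of 30 measured genes 15 rose and 5 fell, 20 in all adjusted over the list alone (median log2 difference 0.33, camera adjusted p = 0.0440; adjusted p = 0.464 with an estimated correlation). Cdkn1a, the p53-induced inhibitor of the cell cycle, rose from 2.85 ± 0.723 to 16.5 ± 1.70 CPM, Zmat3 from 4.43 ± 0.732 to 19.0 ± 0.445 CPM and Gtse1, which is also a gene of G2 phase, from 24.1 ± 1.55 to 49.4 ± 1.75 CPM. Ei24, Rrm2b, Aen, Perp and Ercc5, a DNA repair nuclease, were the 5 that fell, and the Perp call was lost without each library in turn other than CDKO replicate 3 (limma adjusted p from 0.0514 to 0.116), by edgeR (adjusted p = 0.0808) and DESeq2 (adjusted p = 0.0688), with quantile normalization and with no filter. Leaving out 1 library at a time, the median of the p53 list ran from 0.209 to 0.359. The call for the list was lost without control replicate 1 (camera adjusted p = 0.0520) or control replicate 3 (camera adjusted p = 0.0558), where the medians were 0.27 and 0.326. It was lost with a mean of at least 10 CPM, where the median was 0.12 (camera adjusted p = 0.660, and 2.42e-05 to 0.660 over its alternatives, fry included), or at least 50 reads (median 0.24). It was lost as well with TMM scaling (median 0.344, camera adjusted p = 0.0505) and with the correction for GC content and length (median 0.345, camera adjusted p = 0.0854). These 2 medians were no smaller, but the GC and length correction moved the median of all tested genes from -0.0241 to 0.0522.

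**Figure D3:**
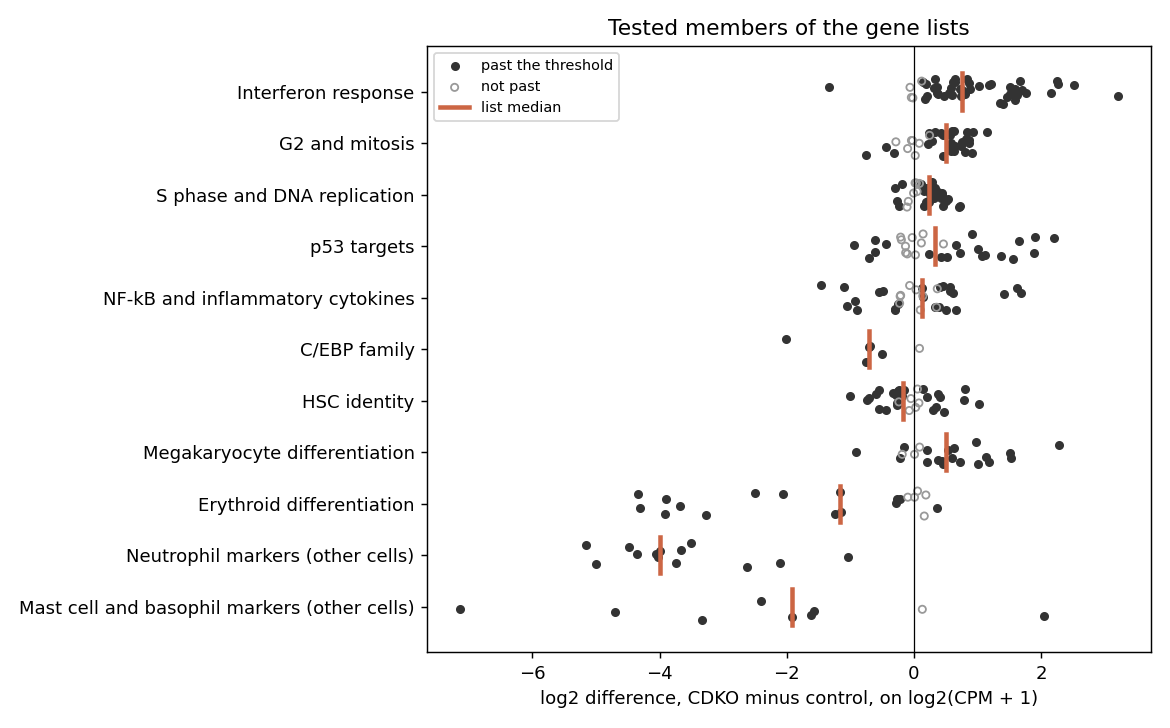
Log2 difference, CDKO minus control, of each tested member of 11 gene lists (points), filled where the gene passed the limma threshold, with the median of each list as a bar. The median was 0.75 for interferon response, 0.51 for G2 and mitosis, -1.16 for erythroid differentiation and -3.99 for neutrophil markers.

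As measured against other genes, 10 of the 30 gene lists tested passed camera with its preset correlation of 0.01, and 0 of the 30 passed with an estimated correlation. The counts of genes above come from the limma test of each gene and do not depend on that setting.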

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

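The comparison of date-named genes with the control pools was chosen after the data were seen. Of the 12 genes whose symbols had been turned into dates, 3 were above the level of the control pools in all 3 CDKO pools. The first stood at 2.37 ± 0.260 CPM in CDKO and 0.556 ± 0.285 CPM in control pools, the second at 137 ± 10.8 and 102 ± 4.61 CPM, and the fifth in order of the table at 210 ± 3.52 and 201 ± 8.01 CPM (SD, n = 3). In 4 others all 3 CDKO pools were below the control pools: the eighth stood at 94.96 ± 11.2 CPM in CDKO and 118 ± 7.98 CPM in control pools, the ninth at 4.11 ± 0.383 and 7.36 ± 0.450 CPM, the tenth at 30.6 ± 1.86 and 56.4 ± 1.80 CPM, and the eleventh at 0.807 ± 0.304 and 2.78 ± 0.249 CPM. Among all tested genes the groups did not overlap for 70.6%, so such a separation does not set these genes apart. These differences were not tested, and the genes cannot be identified here. Groups of 3 libraries were not tested for a library far from the rest.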

How the results depend on the processing

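The filter of 10 CPM and the correction for GC content and transcript length were chosen after the data were seen. Of 180 genes tested that the rule names or the text adds, 160 kept their direction and side of the threshold under every alternative that tested them, 17 changed side and 4 changed direction. The 4, none past the threshold where reversed, were Mki67 (-0.0254 to 0.0757 leaving out 1 library), Parp14 (-0.0393 to 0.0173 leaving out 1 library, 0.0895 after the GC and length correction), Isg20 (0.000425 after that correction) and Ddx3y (0.000549 after it). Nr4a1 (adjusted p from 0.000673 to 0.0105) and Cebpa (at most 0.000135) stayed past the threshold wherever tested, and Cebpa was not tested at 10 CPM. The count of genes past the threshold was 3999 with a 1.5-fold minimum, which lowers it by construction, 8255 to 8708 leaving out 1 library, 6576 of 9886 at 10 CPM, 9199 after the GC and length correction, 8789 by edgeR and 8791 by DESeq2. With replicate number as a block 9242 genes passed, 8995 of them among the 9097, and 10 lists passed; among named genes only Nr4a2 changed side (limma adjusted p = 0.0314; over its alternatives 0.0115 to 0.216).

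With an estimated correlation, interferon response (median 0.75, adjusted p = 0.430), G2 and mitosis (0.51, adjusted p = 0.647) and S phase (0.24, adjusted p = 0.633) lost their calls by camera. That setting changes the degrees of freedom as well as the correlation. For ribosome biogenesis the estimated correlation, -0.00275, lay under the preset 0.01, yet its camera p before adjustment rose from 0.00728 to 0.0390. A higher correlation therefore did not raise that p. For the other lists, which of these changes ended a call was not tested. With an estimated correlation the smallest camera p before adjustment was 0.0326, for interferon response. The C/EBP family (-0.70) and HSC identity (-0.17) passed fry in both forms (directional adjusted p = 0.0019 and 0.0140), and NF-kB (0.12) passed its mixed form alone, which asks another question than camera. Of the lists past camera, p53 targets, ribosome biogenesis and T and NK markers lost their call under some other alternative. Median differences that turned sign, none past the threshold, were STAT signalling (0.10 after the GC and length correction, and -0.0553 to 0.0122 leaving out 1 library), immediate early genes (-0.0130 to 0.113), lymphoid priming (-0.0191 to 0.0763) and endothelial markers (-0.0277 to 0.223) leaving out 1 library, B cell markers with no filter (0.0923), and myeloid differentiation (0.13) and multipotent progenitor markers (0.0176) at 10 CPM. The cause was not tested, beyond the different genes that a filter admits. Genes and lists left without tested members by the filters of 50 reads and 10 CPM gave no value there. Alternatives planned for a table of raw counts, or for one with no values per library, did not apply.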

Other observations

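The tests of a lower share of HSC, of neutrophil-lineage cells and of Cre activity were chosen only after the results they measure were seen, and the correction for GC content and transcript length was added after the data were seen.

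Of 28 genes of ribosome biogenesis 16 rose and 3 fell (median log2 difference 0.14, camera adjusted p = 0.0251; adjusted p = 0.430 with an estimated correlation), a call lost without control replicate 3 (median 0.12, camera adjusted p = 0.0558; 1.29e-05 to 0.430 over its alternatives, fry included), at 10 CPM (median 0.144) and with quantile scaling (median 0.133). Ddx21, a nucleolar helicase, rose from 168 ± 9.36 to 238 ± 6.27 CPM, and Gnl3, Ppan and Polr1c fell. The Polr1c call was lost without control replicate 3, where the log2 difference was -0.137 in place of -0.153 (limma adjusted p = 0.0554; 0.00893 to 0.0696 over its alternatives), and the Ppan and Polr1c calls after the GC and length correction (log2 difference -0.109 and -0.110). Of 17 genes of G1 cyclins, E2F factors and MYC 7 rose and 3 fell, with no call as a set (median 0.08, camera adjusted p = 0.318). Myc, which drives growth, fell from 505 ± 31.7 to 382 ± 7.66 CPM, with Ccnd1 and Ccne1, while Cdk4 rose from 391 ± 5.33 to 511 ± 12.6 CPM. Of 32 DNA repair genes 14 rose and 10 fell (median 0.09, camera adjusted p = 0.440). Atm, the kinase that senses double-strand breaks, fell from 135 ± 5.84 to 56.3 ± 7.15 CPM and Prkdc, another kinase of break repair, from 56.2 ± 2.44 to 20.9 ± 3.91 CPM, while Xrcc2 rose from 13.7 ± 1.53 to 39.7 ± 3.55 CPM. Of 24 regulators of apoptosis 13 rose and 5 fell (median 0.25, camera adjusted p = 0.108): Casp8 rose from 140 ± 4.91 to 224 ± 6.02 CPM, and Birc2, Apaf1, Cflar and Xiap were among those that fell.

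Signalling genes were mixed. Of 21 immediate early genes 9 rose and 6 fell (median 0.09, camera adjusted p = 0.440): Ier5 rose from 7.75 ± 0.275 to 34.1 ± 1.02 CPM and Jun from 8.64 ± 0.920 to 29.8 ± 2.77 CPM, while Atf3 fell from 3.11 ± 0.201 to 0.510 ± 0.143 CPM. Of 22 genes of STAT signalling 8 rose and 9 fell (median -0.04, mean 0.04, camera adjusted p = 0.896), with Jak1 falling from 866 ± 21.9 to 598 ± 3.45 CPM and Bcl2l1 rising from 71.6 ± 5.33 to 110 ± 3.52 CPM. Of 21 antioxidant genes 10 rose and 7 fell (median 0.12, camera adjusted p = 0.440), with Hmox1 rising from 11.1 ± 1.97 to 32.7 ± 2.64 CPM. Of 14 macrophage and monocyte markers 10 fell and 4 rose (median -0.63, camera adjusted p = 0.281). Fn1 fell from 14.9 ± 0.391 to 0.583 ± 0.584 CPM, while Csf1r and the complement genes C1qa, C1qb and C1qc rose, C1qb without a call by edgeR (adjusted p = 0.0509; 0.00117 to 0.0509 over its alternatives). Of 6 measured T and NK cell markers 4 rose (median 0.72, camera adjusted p = 0.0251; adjusted p = 0.464 with an estimated correlation), namely Gzmb, Cd4, Klrb1c and Klrd1, with Klrb1c the highest of them at 12.97 ± 1.79 and 22.2 ± 1.91 CPM; that list was not called at a mean of 50 reads (median 1.16, camera adjusted p = 0.0560) or after the GC and length correction (median 0.75, camera adjusted p = 0.0533). Of 11 endothelial and stromal markers 4 rose, Col1a1, Kdr, Col3a1 and Pecam1, and 3 fell, Col1a2, Cd36 and Stab2, the last without a call under quantile scaling (log2 difference -0.409, limma adjusted p = 0.0729) or after the GC and length correction (log2 difference -0.378, limma adjusted p = 0.0787; 0.0111 to 0.0787 over its alternatives). Median and mean differed in sign, with no call by camera, for CDK inhibitors (-0.11 and 0.09), lymphoid priming (0.03 and -0.18), heat shock genes (0.10 and -0.0043) and STAT signalling; camera took the direction of the mean for the first 2, and of the median for the other 2.

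The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 9097 genes past the threshold and the highest of the others 0, and the real division gave 10 gene lists and the highest of the others 8; 1 of 10 divisions gave as many genes, and 1 of 10 as many lists. Divisions that mix the groups still carry part of the difference between them, and they place the rest within their groups, where it widens the spread. The counts of the other divisions are therefore no benchmark for chance.

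Among tested genes 92 had a mean of at least 5 CPM in one group and under 0.5 CPM in the other, 31 of them higher and 61 lower in CDKO pools. Chance loss of transcripts in low-input amplification is argued against: one library against 2 of the other group showed 63 to 169 such genes, against 0 to 2 for 2 of its own group, a ratio of 31.5 between the lowest and the highest. Strain variants carried along with the insertion at Rosa26 are argued against as the whole cause, since 0% of the 91 such genes with coordinates lay within 10 Mb of Gt(ROSA)26Sor, against 0.738% of all tested genes (Fisher's exact test, two-sided, p = 1). Strain variants elsewhere and the deletion of Nr4a1 itself stay open and were not tested, and the labels name no preparation batch.

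Markers of other blood cells moved apart in CDKO pools. A lower share of HSC in the control pools is argued against, since it lowers all of these markers alike in CDKO, while the megakaryocyte median of 0.50 lay above the neutrophil median of -3.99 (permutation test across genes, which are not independent replicates, two-sided, p = 1e-05, the smallest that 100000 permutations can give); the megakaryocyte list took the place of the T and NK list, most of whose genes lie near the floor, after values were seen. Neutrophil-lineage cells in differing amounts stay a candidate explanation for the neutrophil markers: within genotypes their mean correlation between pools was 0.724, at percentile 100 of 10000 random lists of like expression (highest 0.434), and 12 of 13 were highest in CDKO replicate 3, with S100a8 at 123 and 6.90 CPM and S100a9 at 129 and 4.497 CPM in control and CDKO pools. Shared regulation that varies between pools of a genotype gives such a correlation too and was not tested. The fall of Cebpa between groups is removed with the group means and cannot give it. Whether that fall lowered the neutrophil markers between groups was not tested. Nor was it tested whether neutrophil-lineage cells, rather than HSC, held part of the Cebpa reads in the control pools. The markers of the sort are not stated, a gate against mature lineages would remove such cells, and how many of the 13 genes HSC themselves express was not measured here; 0 of them stand in another list.

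Of 47 interferon response genes 42 were higher in CDKO pools and 1 was lower, and of 30 p53 targets 15 were higher, 5 were lower and 10 did not pass. For the interferon list GC content or transcript length bias is argued against, since 105% of its median was kept after correction of each library, with 99.1% of tested genes covered. Against other genes the interferon list still passed after it (camera adjusted p = 2.05e-14). For p53 targets the median was 0.33 before and 0.35 after that correction. The call ended as the camera adjusted p went from 0.0440 to 0.0854, so that bias stays open for that list. The median of all tested genes moved from -0.0241 to 0.0522 with the same correction, so the kept medians of both lists include that shift. Cre activity and the deletion of Nr4a1 cannot be told apart as sources of the p53 median of 0.33, since no group had Cre with Nr4a1 intact, and the same holds for the interferon genes. A response of HSC to the loss of Nr4a1 in animals without Nr4a3 is the biological explanation that the design names, and it stays open and untested.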
